A study of Mus musculus with 2 samples.

How the data were processed

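Total RNA of mouse cerebral cortex was measured on 2 oligonucleotide arrays, 1 from presenilin conditional double knockout (PS cDKO) mice and 1 from control mice, both at 6 months of age per the labels. The labels do not say whether an array was hybridised with RNA of 1 animal or of a pool, and they give no batch, sex or scan information.

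The deposited table holds 1 linear array intensity per probe set and array, with 12418 probe sets. The software, the summary method, the background step and the scaling behind these intensities are not given in the sources used here. Negative intensities occur in the deposited table, 13 on the control array and 18 on the PS cDKO array, so some subtraction had been applied before deposit. The medians of the deposited intensities were 300 and 305, so a common scaling by the authors is possible, but no source states it. No detection calls and no counts were used here, so the precision is limited by the number of arrays, and no confidence interval or p-value for a difference between the genotypes can be had from 1 array per group.

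Probe sets were named through a platform annotation that can be old. In it 10829 probe sets had 1 gene symbol, 396 had several and 1193 had none, and only those with 1 symbol entered the gene comparison. They stood for 8251 genes, of which 8237 had their gene ID in a RefSeq gene table of the assembly GRCm38.p6, used for names only. The build behind the probe sets is not given in the sources used here, so no coordinates are printed.

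The log2 ratio is PS cDKO over control throughout. The PS cDKO array was scaled so that the median log2 ratio was 0 over probe sets ranked above the median on both arrays, which added 0.034 on the log2 scale. Intensities below the 40th percentile of both scaled arrays pooled, a signal of 232, were then set to that floor, and log2 was taken. A probe set at the floor on both arrays has no ratio, and one at the floor on 1 array has a bound, written "at least". A gene's log2 ratio is the mean over its probe sets above the floor on both arrays, or over its bounded probe sets if it has no other. This gave 5885 measured genes, 5414 of them above the floor on both arrays and 471 with a bound.

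Genes were counted by size, at 2-fold or more, with no test. Before the data were examined, 42 gene lists for cortical cell types, glial activation, presenilin biology, synapses, stress and metabolism, and for blood, meninges, choroid plexus and neighbouring brain regions, were fixed. A list's median log2 ratio was set against 10000 random lists of the same size matched on signal in 20 bins, and a list was said to stand apart above the 97.5th or below the 2.5th percentile. This describes these 2 arrays and is not a test between genotypes. Of the lists, 39 had at least 4 measured genes, so about 2 would stand apart by chance if lists were independent. The lists of γ-secretase components, oligodendrocyte precursor markers and sex-linked genes had too few. A list of genes of other organs was added after the data were seen. The rule for named genes, fixed beforehand, took Psen2, the 12 highest and 12 lowest genes measured on both arrays, up to 4 members of each list with the largest absolute log2 ratio, and the 5 brightest bounded genes in each direction. A further item of the rule is not reported here. Genes named outside this rule are marked as chosen after their values were seen. For named genes, the number of the 500 genes nearest in signal with an absolute log2 ratio as large, the gene itself included, is given as a description.

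In data simulated for the PS cDKO against control comparison with 5821 genes, all 100 genes changed by 1.5 and all 100 changed by 2 on the log2 scale were recovered at 2-fold or more. None of 5621 unchanged genes was. The changed genes were drawn only from those with a single probe set and a control signal above 2 times the floor. Recovery of genes nearer the floor was thus not simulated. Of 100 unchanged lists of 20 genes, 7 stood apart, and of 100 lists shifted by 0.3, 100 were called higher. The 0.3 was added to every member alike, so recovery of smaller or mixed shifts was not simulated. Of the lists that stood apart in the real data, only the reactive astrocyte list had a median of that size. The simulated noise came from pairs of probe sets of the same gene and holds no variation between animals.

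The alternatives tried were the intensities as deposited, quantile normalization, a lowess fit of the ratio on signal (span 0.3), floors at the 20th and 60th percentiles, no floor, the brightest probe set of a gene, leaving out suffixed probe sets, other fold thresholds, the mean of a list, and only genes above the floor on both arrays. Suffixed probe sets are those whose identifier carries _f, _r, _i, _s, _x or _g before the ending _at. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.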

Results

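The comparison asked how gene expression in the cerebral cortex of mice lacking presenilin differed from that of control mice at 6 months of age. Presenilins are the catalytic subunits of γ-secretase, the membrane protease that cleaves the amyloid precursor protein and Notch. The data were 1 array per genotype, with 12418 probe sets each. The median intensity was 300 in the control and 305 in the PS cDKO, and 59.1% and 60.9% of probe sets lay above the floor. Log2 signals of the 7091 probe sets above the floor on both arrays correlated with r = 0.96 across probe sets, which are not independent replicates. With no replicate array, no difference below can be set against variation between animals, and no p-value is given.

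Psen2, a presenilin gene, was examined first. Its probe set had an intensity of 105 in the control and 94.9 in the PS cDKO, both below the floor of 232, so it gave no ratio and no check of the genotype. The position of the Psen2 probes relative to the deleted part of the gene is not given in the sources used here. Of the other γ-secretase subunits, Psenen was 1.08-fold and Aph1a 1.12-fold of the control level. Among 500 genes of like signal, 306 and 235 differed as much.

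Gfap, the intermediate filament of astrocytes and a marker of their activation, showed the largest difference of all genes measured on both arrays. Its signal was 458 in the control and 2145 in the PS cDKO, a 4.68-fold difference, and a further probe set of the gene was at least 6.24-fold higher. C1qa, a chain of the complement initiator C1q, was 2.11-fold higher (532 against 1124). Impact, a regulator of translation, was 2.07-fold higher. Cd9, a tetraspanin, was at least 2.49-fold higher, Kif5b, a kinesin heavy chain, at least 2.18-fold, and Cd74, the MHC class II invariant chain, at least 2.13-fold. No other gene of the 5885 measured was at least 2-fold higher with bounds counted at their limit; with no floor 13 of the 471 bounds were. With a floor at the 60th percentile the bounds for Cd9, Kif5b and Cd74 were 1.43-fold, 1.25-fold and 1.22-fold, and 2 genes were at least 2-fold higher. A bound falls as the floor rises, and with no floor the 3 genes were 3.27-fold, 3.05-fold and 2.18-fold higher.

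Another 6 genes were at least 2-fold lower in the PS cDKO. Tshb, a pituitary hormone subunit, was 2.71-fold lower (1302 against 481), the potassium channel subunit Kcne1 2.25-fold and the kinase Mast3 2.11-fold lower. Nmi was at least 4.48-fold lower (1039 against 33.9), and the transcription factor Foxo3 at least 2.24-fold lower. Sacm1l was counted from a bound of 2.02-fold, but its deposited PS cDKO intensity was -2207.57, which cannot be read as a level, so that 5 genes remain without it. With a floor at the 60th percentile the bounds were 2.58-fold for Nmi, 1.79-fold for Kcne1, 1.29-fold for Foxo3 and 1.16-fold for Sacm1l, and 2 genes were at least 2-fold lower. The other 9 of the 12 lowest genes measured on both arrays were Kalrn, a synaptic guanine nucleotide exchange factor (1.92-fold lower), Sf3b5, a splicing factor (1.88-fold), Ttr (1.84-fold), 1110008P14Rik (1.77-fold), Samm50, of the mitochondrial outer membrane (1.71-fold), 6330403K07Rik (1.70-fold), Dstn, an actin-depolymerising factor (1.69-fold), Atp5e (1.69-fold) and Npdc1 (1.68-fold). With no floor Kalrn was 1.19-fold lower and 6330403K07Rik 1.01-fold higher. These means took in further probe sets below the main floor, such as that of Kalrn at 41.4 against 56.4. With a floor at the 60th percentile Samm50 and Atp5e gave bounds of at least 1.02-fold and 1.05-fold lower. The counts depended on the floor: with no floor, 103 genes were at least 2-fold higher and 46 at least 2-fold lower. Among genes measured on both arrays, 98.4% differed by less than 1.5-fold, and the robust SD of the log2 ratio across genes was 0.23, or 1.17-fold.

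**Figure D1:**
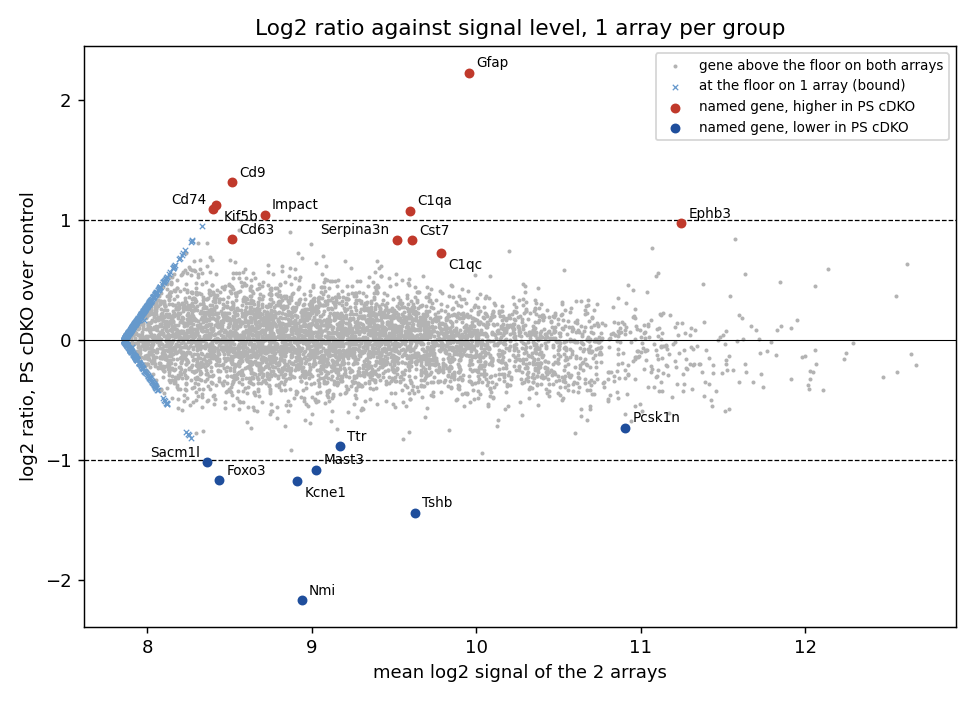
Log2 ratio of PS cDKO over control (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis), 1 grey point per gene above the floor on both arrays and 1 cross per gene at the floor on 1 array, whose ratio is a bound. Large points are named genes, and dashed lines mark 2-fold; Gfap lies highest at 2.23 and Nmi lowest at -2.17.

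Other genes among the 12 with the highest ratios included several of microglia, macrophages and reactive astrocytes. Ctss, a lysosomal protease of microglia, was 1.79-fold higher (545 against 978). Cst7, a cystatin of activated microglia, was 1.78-fold, Cd63, a lysosomal tetraspanin, 1.79-fold, and Serpina3n, a protease inhibitor of reactive astrocytes, 1.79-fold higher. Between 2 and 5 of the 500 genes nearest in signal differed as much as each of these. The remainder of the 12 were Ephb3, an ephrin receptor (1.96-fold), Muc5ac, a mucin (1.89-fold), Pnliprp1, a pancreatic lipase homologue (1.86-fold), Lrrc8c (1.79-fold) and Acrbp (1.76-fold). With a floor at the 60th percentile Cd63 and Acrbp gave bounds of at least 1.21-fold and 1.04-fold higher, and Impact one of 0.58 on the log2 scale. Kif20a and Prc1 were at least 1.78-fold and at least 1.93-fold higher. Their bounds were 1.03-fold and 1.11-fold with a floor at the 60th percentile, and with no floor they were 1.40-fold and 3.28-fold higher.

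The reactive astrocyte list stood apart upward. Of its 14 measured genes 12 were higher, with a median log2 ratio of 0.30, above the 10000 random lists at the 100th percentile. Besides Gfap and Serpina3n, Cd14, an endotoxin co-receptor, was 1.53-fold and Vim, another intermediate filament, 1.38-fold higher. General astrocyte markers did not stand apart, with a median of 0.06 over 16 genes, although the water channel Aqp4 was 1.45-fold and the connexin Gja1 1.46-fold higher. The 2 probe sets of Gja1 disagreed, with log2 ratios of 0.02 and 1.08.

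Microglial genes also lay higher. Of 24 measured microglia markers 21 were higher, with a median log2 ratio of 0.17 at the 99.9th percentile. Itgam, the integrin CR3 subunit, was 1.61-fold, Tyrobp, a signalling adaptor, 1.47-fold and Lcp1, an actin bundler, 1.45-fold higher. Of 21 genes of the disease-associated microglia list 17 were higher, with a median of 0.19. Cd52 was 1.33-fold higher and Apoe, the main brain apolipoprotein and also a member of other lists, 1.29-fold higher (5282 against 6799). The list of interferon-response genes had a median of 0.17 at the 98.9th percentile, with 12 of 17 genes higher. Of the 16 above the floor on both arrays Gbp2 was the highest at 1.36-fold; Igtp was at least 1.24-fold higher, and 1.63-fold with no floor. Its position was lost under both other floors, with medians of 0.051 at the 20th and 0.036 at the 60th percentile. Genes of other organs, a list added after the data were seen, also lay higher, with a median of 0.11 over 48 genes at the 99.6th percentile. Of the genes above the floor on both arrays, 0 of 44 in this list were at least 1.5-fold higher, against 7 of 54 in the reactive astrocyte and both microglia lists. Among all 5414 such genes 48 were. Among the bounds 1 gene of each set did so with no floor, Slc12a3 (154 against 235), chosen after its values were seen, and Cd9.

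Members of immune lists that did not stand apart as a whole differed widely. In the complement list C1qa and C1qc were 2.11-fold and 1.66-fold higher, whereas the median over 11 genes was 0.05. For C1qb the probe set above the floor on both arrays was 1.20-fold and a further one at least 2.90-fold higher. All 8 MHC class II genes were higher, with a median of 0.14 and only Cd74 past 2-fold. MHC class I and antigen-processing genes had a median of 0.09, with Tapbp at 1.18-fold and B2m at 1.16-fold. Cytokines and chemokines had a median of 0.10. Within them Cx3cl1, a neuronal chemokine, was 1.49-fold lower (3627 against 2435), while Tnf was 1.26-fold and Ccl12 1.29-fold of the control level. After lowess and with no floor Cx3cl1 was 1.14-fold and 1.16-fold lower. There a further probe set near the main floor (228 against 252) entered its mean. Lysosomal proteins had a median of 0.07 over 27 genes, with Cd63 and the protease Ctsd (1.39-fold) among the higher ones.

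**Figure D2:**
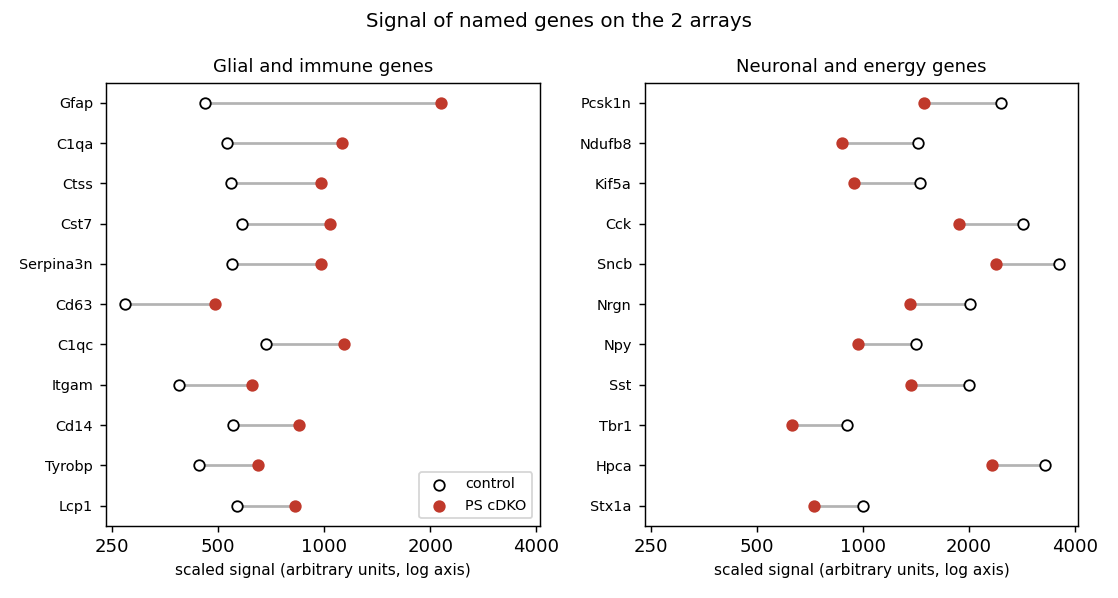
Scaled signal in arbitrary units (log axis) of 22 named genes on the control array (open circles) and the PS cDKO array (filled circles), 1 array each, chosen from those described in the text as examples of either direction. The left panel holds glial and immune genes, with Gfap from 458 to 2145, and the right panel neuronal and energy genes, with Nrgn from 2014 to 1356.

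Presynaptic genes and markers of excitatory neurons lay lower. Of 20 presynaptic genes 17 were lower, with a median log2 ratio of -0.25 at the 0.05th percentile. Sncb (β-synuclein) was 1.51-fold, the active zone protein Pclo 1.39-fold, the vesicle fusion protein Stx1a 1.38-fold and the endocytic GTPase Dnm1 1.32-fold lower. Markers of excitatory cortical neurons had a median of -0.21, with 14 of 20 lower. In that list the calmodulin-binding protein Nrgn was 1.49-fold (2014 against 1356), the transcription factor Tbr1 1.43-fold, the calcium sensor Hpca 1.41-fold and the kinase subunit Camk2b 1.40-fold lower. None of the 19 above the floor on both arrays reached 1.5-fold in its gene value. Among them Kcnab2, chosen after its values were seen, had a gene value of -0.27 from 1 probe set. A further Kcnab2 probe set, at the floor in the PS cDKO, had a log2 ratio of at most -1.86 (842 against 186). Cytoskeletal genes and tau kinases had a median of -0.16 over 23 genes, with the kinesin Kif5a 1.58-fold and the neurofilament Nefl 1.39-fold lower. Without suffixed probe sets that median was -0.050, at the 30.5th percentile.

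Inhibitory neuron markers did not stand apart (median -0.04), but 3 abundant neuropeptides lay lower: Cck by 1.52-fold, Npy by 1.47-fold and Sst by 1.47-fold. The granule protein Pcsk1n was 1.66-fold lower (2467 against 1488), in a neuropeptide and secretory granule list with a median of -0.04. Among GABA receptor genes Gabrd was 1.64-fold lower, with a list median of -0.10. Glutamate receptor and postsynaptic genes had a median of -0.07, with the calcineurin subunit Ppp3ca 1.31-fold lower and Gria1 at log2 ratios of -0.10 and 0.95 in its 2 probe sets. Calcium-handling genes had a median of -0.05, with the calcium release channel Itpr2 1.66-fold higher and Cacna1g 1.39-fold lower.

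Genes of energy metabolism and protein turnover were lower as groups. All 15 glycolysis genes were lower, with a median log2 ratio of -0.27, among them Ldhb by 1.39-fold and the hexokinase Hk1 by 1.38-fold. With no floor Ldhb had a log2 ratio of -0.0017, where a further probe set below the main floor (39.2 against 54.5) entered its mean. Of 23 respiratory chain genes 19 were lower, with a median of -0.26. The complex I subunits Ndufb8 and Ndufs3 were 1.65-fold and 1.51-fold lower and Sdhb 1.40-fold lower, whereas Cox5a was 1.54-fold higher. Atp5e, of the ATP synthase, was 1.69-fold lower. Ribosomal protein genes had a median of -0.22, with Rps7 1.34-fold lower, and proteasome genes a median of -0.18, with Psma7 1.49-fold and Psmd4 1.44-fold lower. The ribosomal list no longer stood apart without a floor, at -0.12 and the 9.56th percentile. Altogether 4 lists stood apart upward and 7 downward out of 39.

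**Figure D3:**
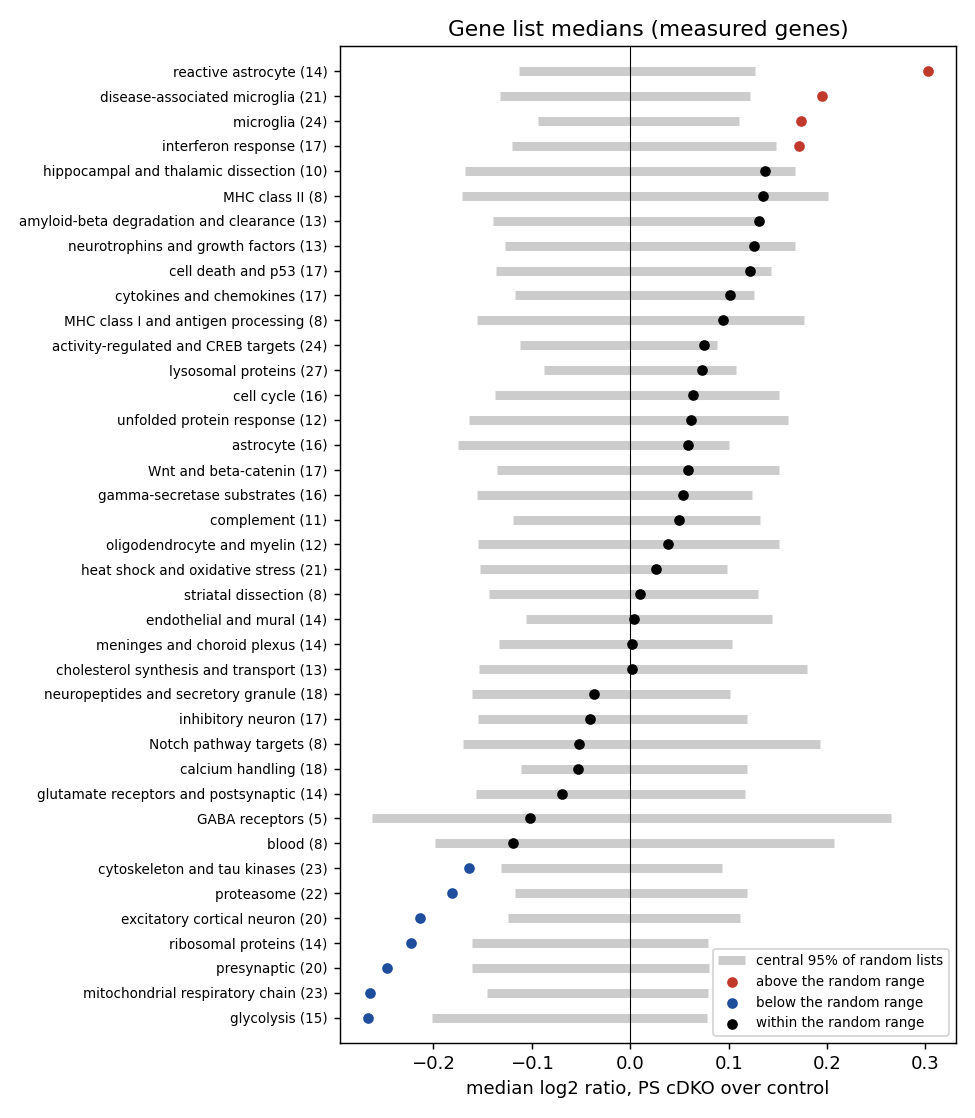
Median log2 ratio of PS cDKO over control (horizontal axis) for the 39 gene lists, with the number of measured genes in brackets. Grey bars span the central 95% of 10000 random lists matched on signal, red and blue points lie outside it and black points within it; reactive astrocyte genes lie highest at 0.30 and glycolysis genes lowest at -0.27.

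Genes tied to presenilin function did not stand apart. The γ-secretase substrates had a median of 0.05 over 16 genes, of which 9 were higher. App, the amyloid precursor, was 1.34-fold lower (5101 against 3816) and Aplp2 1.24-fold lower. Sdc3 was 1.28-fold and Cdh2 at least 1.31-fold higher. Notch pathway targets had a median of -0.05 over 8 genes, with Dtx1 1.31-fold and Hey1 1.22-fold lower. Genes of amyloid-β degradation and clearance had a median of 0.13, just inside the range of random lists at the 97.4th percentile, with Mmp2 1.40-fold higher and Ece1 1.45-fold lower. Activity-regulated genes and CREB targets had a median of 0.07 over 24 genes. The transcription factor Egr1 was 1.20-fold and the clock gene Per1 1.38-fold lower, and both Fos probe sets were below the floor on both arrays; Fos was chosen after its values were seen. Neurotrophins and growth factors had a median of 0.13, with Igfbp2 1.60-fold lower, and Wnt and β-catenin genes 0.06. Cell death and p53 genes had a median of 0.12, with Bad, a pro-apoptotic factor, 1.51-fold higher and the calpain Capn2 1.45-fold lower.

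The stress lists and the lists for other brain cells, blood, meninges and neighbouring regions stayed within the range of random lists. The unfolded protein response had a median of 0.06, with the chaperones Pdia3 and Hspa5 at 1.52-fold and 1.36-fold of control, and heat shock and oxidative stress genes 0.03, with Gpx1 1.45-fold higher. Cholesterol genes had a median of 0.0013 and cell cycle genes one of 0.06. Oligodendrocyte and myelin genes had a median of 0.04 over 12 genes, although the myelin gene Mobp was 1.36-fold lower with all 4 probe sets lower. Endothelial and mural genes had a median of 0.0034, with the tight junction gene Cldn5 1.35-fold lower. Meningeal and choroid plexus genes had one of 0.0022, with the choroid plexus transcript Ttr 1.84-fold lower (782 against 425), the only one of the 500 genes nearest in signal to differ as much. Igfbp2, also in that list, was 1.60-fold lower. Blood genes had a median of -0.12, with the globin Hba-a1 1.37-fold lower, striatal genes 0.01, and hippocampal and thalamic genes 0.14, with Wfs1 1.43-fold higher. Of sex-linked genes, Xist and Eif2s3y were below the floor on both arrays; they were chosen after their values were seen.

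Genes with more than 1 probe set gave the only repeated measurement. Over 749 genes, the log2 ratios of the 2 brightest probe sets correlated with r = 0.24 and rho = 0.24 across genes, and 57.9% of pairs had the same sign. The pairs include suffixed probe sets, which may overlap with others, so that not all pairs are independent measurements. Without suffixed probe sets the correlation was lower, as given below. The SD of a single probe set's log2 ratio estimated from these pairs was 0.21. The robust SD of 0.23 across genes is an unlike measure, since a gene value can be a mean of several probe sets.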

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

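With 1 array per genotype no array could be left out, and no paired analysis was possible because each group holds 1 array. Scaling moved the median of all genes by less than 0.1 in every setting. The reactive astrocyte, microglia and disease-associated microglia lists stayed above, and the excitatory neuron, presynaptic, respiratory chain, glycolysis and proteasome lists below, the range of random lists under all 10 alternatives. Their extremes were 0.27 to 0.41, 0.14 to 0.22 and 0.16 to 0.27 upward, and -0.25 to -0.11, -0.29 to -0.22, -0.33 to -0.21, -0.30 to -0.21 and -0.21 to -0.17 downward. Over the 39 lists, 367 of the alternative results stayed above, below or within the range of random lists as in the main setting. Another 14 newly stood apart and 8 no longer did. Medians within the range could still change sign. The causes were not tested.

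The number of genes at least 2-fold higher, 6, became 18 with a floor at the 20th percentile, 2 at the 60th and 103 with no floor. The number at least 2-fold lower, also 6, became 12, 2 and 46. At 1.5-fold the counts were 66 higher and 48 lower, and at 3-fold 1 and 1. The interferon list no longer stood apart with floors at the 20th percentile (0.051) and the 60th (0.036), with no floor (0.067) or with genes above the floor on both arrays (0.12). The cytoskeletal list no longer did after quantile normalization (-0.11), without suffixed probe sets (-0.050) or with genes above the floor on both arrays (-0.12), nor the ribosomal list with no floor (-0.12).

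Lists that newly stood apart upward were amyloid-β clearance (0.29) and lysosomal proteins (0.18) with no floor; cytokines (0.17) and lysosomal proteins (0.17) with the floor at the 20th percentile; cytokines without suffixed probe sets (0.17); astrocyte (0.15) and cell death (0.12) genes after quantile normalization; activity-regulated (0.098) and cell death (0.12) genes after lowess; and complement (0.19), MHC class II (0.26) and lysosomal proteins (0.11) by the mean. Inhibitory neuron (-0.19) and neuropeptide (-0.21) genes did so downward with the floor at the 60th percentile. The correlation between probe sets of a gene was 0.33 with the floor at the 60th percentile, 0.16 with no floor and 0.12 without suffixed probe sets. Of the 34 genes named as highest, lowest or bounds, 6330403K07Rik turned its sign, to 0.015 with no floor, and 9 other named genes did so in at least 1 setting: Aplp2, Bcan, Cdkn1a, Cldn11, Cr1l, Ctsb, Gria1, H2-K1 and Pdgfra. Of 172 named genes 49 moved by more than 0.21, the SD between probe sets, in at least 1 setting, in 80 results, of which 70 came with a changed floor or no floor. With the floor at the 60th percentile Muc5ac gave a bound of 1.29-fold and Gbp2 one of 1.02-fold higher, and Igfbp2 and Psma7 gave bounds of 1.22-fold and 1.14-fold lower. With no floor Itpr2, Bad and Lcp1 were 1.25-fold, 1.22-fold and 1.18-fold higher and Capn2 1.11-fold lower. Each of these genes has further probe sets that the main floor had kept out of its mean.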

Other observations

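The families and tests in this part were chosen after the data were seen, except that the comparisons with genes of other organs and of bright glial genes were set out before their values were known. Of 26 measured Nduf genes, which encode subunits of mitochondrial complex I, 24 were lower in the PS cDKO, with a median log2 ratio of -0.35, below all random lists matched on signal, and Ndufa6 was at least 1.76-fold lower, but only at least 1.01-fold with a floor at the 60th percentile. Subunits of protein phosphatase 2A and calcineurin had a median of -0.29 over 11 genes, with Ppp3r1 at a log2 ratio of -0.46, although Ppp2r2a stood at 0.67. Of 10 cathepsins 7 were higher, with a median of 0.22 at percentile 99.1, among them Ctss, Ctsd and Ctse. All 5 Ywha genes were lower, but their median of -0.09 lay within the range of random lists. Potassium channel genes had a median of 0.0090 over 30 genes and keratins one of 0.014 over 27. Of 905 probe sets with no gene name or several that were above the floor on at least 1 array, 5 were at least 2-fold lower and 0 at least 2-fold higher. The largest difference was at least 6.73-fold lower (1558 against 43.9), more than for Nmi, and another was at least 2.54-fold lower (589 against 33.9). Neither of these probe sets had a gene name.

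The first pattern is the higher signal of reactive astrocyte and microglial genes. A lower share of neurons would raise markers of all other cell types alike. The pooled lists lay 0.18 above the oligodendrocyte and endothelial lists (95% bootstrap interval over genes 0.084 to 0.33), whose pooled median was 0.018. The 3 lists were picked for lying high in these same arrays, so a gap was expected and the comparison does not decide this. A trend of the ratio with signal as the whole cause is argued against by the matching of the random lists on signal. That all 3 lists stayed above the range of random lists after lowess adds little, since the random lists were already matched on signal. A higher unspecific signal on the PS cDKO array remains open for the small shifts. Genes of other organs had a median of 0.11, Hox genes of 0.16 and olfactory receptors of 0.17, above the range of random lists. Keratins, at 0.014, lay within it. The pooled glial lists lay only 0.096 above the other-organ genes (-0.0045 to 0.19). Taken alone, the reactive astrocyte list lay 0.20 above them (-0.040 to 0.39), the microglia list 0.068 (-0.024 to 0.18) and the disease-associated microglia list 0.089 (-0.054 to 0.20). A median cannot speak for single members such as Gfap and Ctss. Of the genes above the floor on both arrays, 7 of 54 glial and 0 of 44 other-organ genes were at least 1.5-fold higher. Of all 5414 such genes only 48 were, so 0 of 44 is little different from genes at large. The glial lists were also picked for lying high in these same arrays, so these counts do not decide the question. Among the bounds Slc12a3 would pass 1.5-fold with no floor, as Cd9 did. The genotype is a candidate cause that 1 array per group cannot test.

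The second pattern is the lower signal of 7 lists: excitatory neuron, presynaptic, cytoskeletal, respiratory chain, glycolysis, ribosomal and proteasome genes. The inhibitory neuron, postsynaptic, GABA receptor and neuropeptide lists did not stand apart. The 7 lower lists all stayed below the range of random lists after lowess, the cytoskeletal and ribosomal lists only just, at percentiles 2.23 and 2.22. After quantile normalization the cytoskeletal list went from -0.16 to -0.11, at percentile 3.78. All 7 lists were set against random lists matched on signal, where the cytoskeletal and ribosomal lists had lain at percentiles 0.59 and 0.26. That both moved up after lowess leaves it possible that the matching did not allow for the whole of a trend with signal. Such a trend stays open for the cytoskeletal and ribosomal lists. For the other 5 lists, which stayed at or below percentile 0.22 after lowess, a trend with signal as the whole cause is argued against. A weaker signal of all abundant transcripts on the PS cDKO array was not decided. Bright astrocyte and oligodendrocyte genes, with a median of 0.044, lay 0.31 above bright genes of these lists (0.18 to 0.45). The 7 lists were picked for lying low in these same arrays, so a gap of this direction was expected. A lower share of neurons may account for the pattern but was not decided either. Proteasome and ribosomal genes, which all cells use, differed from excitatory neuron and presynaptic genes by 0.025 (-0.10 to 0.12). Dissection was looked at only through list medians. Those of striatal (0.01), hippocampal and thalamic (0.14) and meningeal and choroid plexus genes (0.0022) lay within the range of random lists. In the last of these lists Ttr was 1.84-fold and Igfbp2 1.60-fold lower, so that dissection stays open. RNA quality and differences between animals were not tested and cannot be excluded with 1 array per group.

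The third pattern is that large differences of single probe sets were often not matched in size. Of 19 probe sets at least 2-fold different, 8 had another measured probe set of the same gene. Of the 10 comparisons with such a probe set, 40% went the same way by 0.5 or more on the log2 scale. Since the 19 were picked for their size, smaller partners are expected with or without faults of single probe sets, so the share does not decide between them. Yet 9 of the 10 had the same sign, and the third Gnb1 probe set, at 0.47, fell just short of the threshold, so the test speaks to the size of these differences and little to their direction. These comparisons count a pair in both directions where both probe sets differ by 2-fold; of the 8 distinct pairs 2, or 25%, agreed by that threshold and 7 agreed in sign. The pairs that met the threshold were within Gfap and Gnb1, in pairs with a probe set whose identifier suffix marks a possible overlap with others, so that they may not be independent. Kcnab2 had log2 ratios of at most -1.86 and of -0.27, and Gas5 of -1.17 and 0.26; Kcnab2, Gnb1 and Gas5 were chosen after their values were seen. Nmi, whose signal was 1039 in the control and 33.9 in the PS cDKO, had no other measured probe set, so a fault of that probe set and a real difference could not be weighed.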
